A study of Mus musculus with 40 samples.

How the data were processed

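CD4+ T cells were sorted from 10 sources of perfused wild-type mice, per the labels. Cells positive for a Foxp3-Thy1.1 reporter were taken as Treg and negative ones as Tconv, 2000 cells per library, with 3 Treg libraries and 1 Tconv library per source. RNA was made into 3′ mRNA libraries with the QuantSeq kit by Lexogen, per the labels' protocols. The deposited table holds raw gene counts, and per the submitters' processing notes the reads were checked with FastQC and MultiQC, trimmed with Trim Galore, aligned with STAR to mm10 and counted per gene with featureCounts. The same notes name DESeq2 and DESeq without versions, and the values in the table were whole counts with no sign of scaling. The release of the gene annotation is not stated in the labels. The kit reads 3′ ends, so counts are not divided by gene length, and whether strand was used in counting is not stated, so reads of a gene and of an overlapping antisense gene cannot be told apart.

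The table held 55421 genes in 40 columns. Of the gene identifiers, 54587 matched the reference annotation with their version and 55154 could be given a symbol, 267 had none, and 213 shared a symbol with another gene and were kept apart by identifier. Coordinates are those of mm10, counted from 1. Total counts per library ran from 12197980 to 28823493, so that 3 counts, the floor used for genes at 0, stand for well under 1 CPM. Pairs of Treg replicates differed by 21.7 (spleen Treg replicates 2 and 4) to 401 times the variance that counting alone gives, as a chi-square per degree of freedom. The floor of 3 counts is the upper limit, at a confidence level of 95%, that a count of 0 allows, and covers counting error only.

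All comparisons, their tests, the gene lists and the rule for naming genes were fixed before the data were examined. Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM, a trended dispersion was fitted, and the robust quasi-likelihood F test was used, with a Benjamini-Hochberg adjusted p below 0.05 as the threshold for a call. Treg were compared with Tconv over all 40 libraries with the source as an additive factor. The Treg comparisons used 1 fit of the 30 Treg libraries with a mean per source. In that fit the unweighted mean of kidney, liver, lung, pancreas, IEL and LPL was set against the unweighted mean of blood, spleen and lymph node, each of these tissues and Peyer's patch was set against the same reference, and IEL with LPL was set against the other 4 tissues. A gene was called shared when it passed in the same direction in all 6 tissues. Tconv of the 6 tissues were compared with Tconv of blood, spleen and lymph node with 1 library per source as the replicate. The difference of the tissue effect between Treg and Tconv was tested in a fit of all 40 libraries with a mean per source and cell type. Log2 fold changes are given with their standard error, and levels as the mean CPM with the SD over libraries, with the library total multiplied by its TMM factor. Folds against a floor, the levels of Xist and the check of Foxp3 for samples far from their group used CPM without that factor. A fold against a group with 0 counts was taken against 3 counts over the group.

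The grouping of Treg libraries was measured by Euclidean distances of log2 CPM over the 500 most variable genes, with 100000 permutations of the source labels. The 32 gene lists, 11 of them markers of other cell types, were written from general knowledge of the field. They were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one, and adjusted over 384 tests of lists and comparisons. Of these, 225 passed with the preset and 29 with the estimated correlation, and all 29 were among the 225. The p-values printed are those with the estimated correlation. The mean of the early response list per library was taken over log2(CPM + 1), and its relation across sources was tested by permutation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

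Named genes are, for each comparison, the 5 higher and the 5 lower ones with the smallest p among called genes with an absolute log2 fold change of at least 1, and 3 and 2 for single sources. Symbols of predicted genes, immunoglobulin and T cell receptor segments and markers of other cell types were left out. From a list that the text describes, up to 4 members with the smallest p in that comparison could be named, and from a list of other cell types up to 3 with the highest mean CPM. Foxp3 was read in every library. From the shared set, the 10 genes with the largest smallest absolute change over the 6 tissues were named, with markers of other cell types kept.

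The alternatives were DESeq2 size factors, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-voom with quality weights, removal of marker genes of other cell types, a replicate block, other reference sources, summed counts per source, a fold change of at least 2, and the omission of each library. A term for Xist-expressing libraries, the omission of 6 libraries with the last sample numbers, and the shared set without each tissue were added after the data had been seen. The tests were checked on simulated counts with 200 changed genes. Other splits of the same libraries or sources into groups of the same sizes were fitted in the same way, with 15 or 84 splits of sources, and 40, 60 or 100 splits of libraries where there were more. Splits of Treg libraries used a fit with 1 mean per group, which called fewer genes for the real split than the fit with a mean per source. No library was left out of the main comparisons.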

Results

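Polyadenylated RNA was counted by 3′ sequencing in regulatory T cells (Treg, CD4+ cells positive for a Foxp3-Thy1.1 reporter) and in reporter-negative conventional CD4+ T cells (Tconv) sorted from perfused wild-type mice. The cells came from 10 sources. These were blood, spleen, lymph node, Peyer's patch, kidney, liver, lung, pancreas and 2 compartments of the small intestine, the intraepithelial lymphocytes (IEL) and the lamina propria lymphocytes (LPL). Each source gave 3 Treg libraries and 1 Tconv library, which made 30 Treg and 10 Tconv libraries of 2000 sorted cells each. Total counts per library ran from 12197980 to 28823493, and between 14411 and 19167 genes had at least 1 count. The labels do not say which libraries share an animal, so the p-values, SD and SE measure the spread between these samples. The floors used for counts of 0 cover counting error only.

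Foxp3 (ENSMUSG00000039521.13, mm10 chromosome X, 7573644 to 7595245), the transcription factor that defines Treg, was read first as a check of the labels. Levels are given as CPM, the count scaled to the library total times its TMM factor unless stated otherwise. It reached 218.9 ± 64.8 CPM (SD, n = 30) in Treg and 1.27 ± 1.89 CPM (SD, n = 10) in Tconv. The lowest Treg library, lymph node Treg replicate 10, had 65.9 CPM and the highest, IEL Treg replicate 2, had 305 CPM. The highest Tconv library, from lung, had 6.56 CPM, so every library lay on the side its label gives.

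The title of the series speaks of a residency program that tissue Treg share, which first raises the question of how far the tissue of origin separates these cells. Treg libraries grouped by tissue. Over the 500 most variable genes the mean Euclidean distance of log2 CPM was 30.46 between libraries of the same tissue (30 pairs) and 58.29 between libraries of different tissues (405 pairs). The difference of -27.83 had a permutation p of 1e-05, two-sided, the smallest that 100000 permutations can give. The nearest neighbour of 25 of the 30 libraries came from the same tissue. The exceptions joined the gut compartments to each other (IEL Treg replicate 3 and LPL Treg replicate 3), kidney Treg replicate 1 to lung Treg replicate 1 in both directions, and lymph node Treg replicate 6 to spleen. The transcript Gm26917 took 2.23% of counts in kidney Treg replicate 1 and 1.57% in lung Treg replicate 1. The other kidney and lung Treg libraries had at most 0.862%. Principal component 1 held 36.8% of the variance and component 2 held 21.2%.

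**Figure D1:**
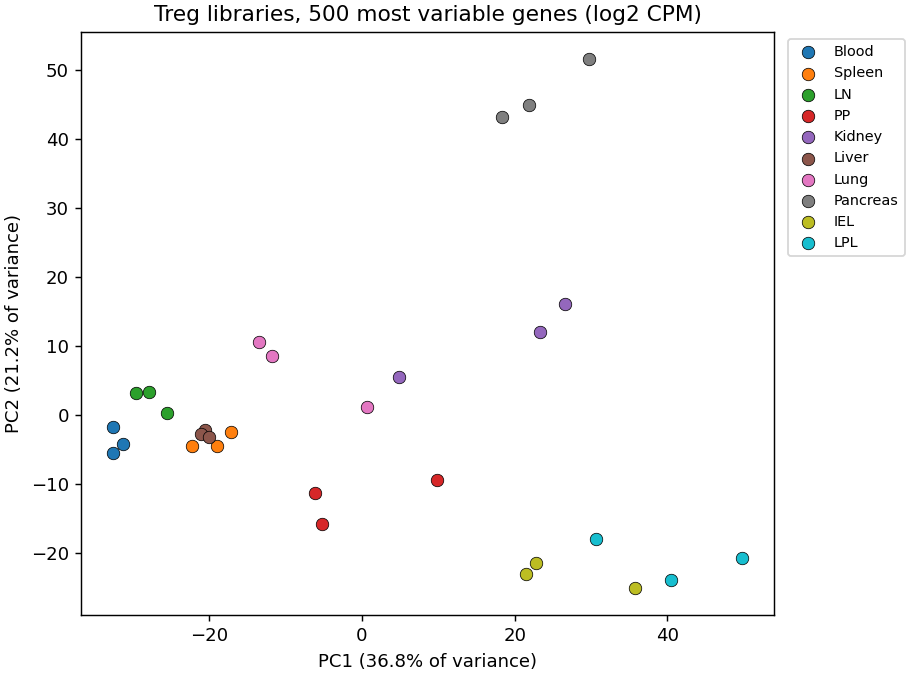
Principal components 1 and 2 (36.8% and 21.2% of the variance) of log2 CPM over the 500 most variable genes in the 30 Treg libraries, one point per library, coloured by tissue. Libraries of the same tissue lie nearest each other for 25 of the 30.

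The comparison of Treg with Tconv asks what sets the reporter-positive cells apart whatever their tissue. Lrrc32 (ENSMUSG00000090958.2, chromosome 7, 98489283 to 98502181), the surface anchor for latent TGF-beta, stood at 535.8 ± 414.1 CPM (SD, n = 30) in Treg and at 2.32 ± 2.17 CPM (SD, n = 10) in Tconv, a log2 fold change of 7.90 ± 0.46 (SE). Foxp3 differed by 7.61 ± 0.41. The transcription factor gene Ikzf4, which encodes Eos, was higher by 4.33 ± 0.32, and the costimulatory receptors Tnfrsf4 (OX40) and Tnfrsf9 (4-1BB) by 3.32 ± 0.22 and 3.15 ± 0.24. In the other direction Cd40lg (ENSMUSG00000031132.1, chromosome X, 57212143 to 57224042), the ligand by which helper T cells license B cells and dendritic cells, had a log2 fold change of -2.21 ± 0.12, with 62.2 ± 42.6 CPM in Treg and 290.6 ± 187.7 CPM in Tconv. Themis, a regulator of T cell receptor signalling, had -1.71 ± 0.09.

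Within tissues, 2565 of 14983 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment. Of these, 1477 were higher and 1088 lower in Treg, and 623 and 370 of them by at least 2-fold. The relaxin family hormone gene Rln3 (log2 fold change 4.54 ± 0.27) and Tmem158 (3.46 ± 0.25) joined Foxp3, Lrrc32 and Tnfrsf4 among the 5 higher genes with the smallest p. The 5 lower ones were Themis, Cd40lg, the membrane protein gene Mctp2 (-2.78 ± 0.16), the heparan sulfate transferase gene Hs3st3b1 (-3.22 ± 0.19) and the sialyltransferase gene St3gal6 (-2.86 ± 0.18). Of the 25 genes of the fixed Treg signature, 24 were higher and 0 lower, and 25 and 0 when adjusted over the list alone, with a median log2 fold change of 3.17 (camera adjusted p = 1.1e-05 with an estimated correlation). Of 15 genes associated with Tconv, 11 were lower and 0 higher (14 and 0 adjusted over the list alone), among them Pde3b, a phosphodiesterase gene, and Dapl1, and the set test held with an estimated correlation (adjusted p = 2.4e-06). Dapl1 (-3.76 ± 0.35) did not pass in DESeq2.

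Killer cell genes lay on the Tconv side. Of 18 cytotoxic granule genes and natural killer receptors, 15 were lower in Treg and 0 higher (16 and 0 adjusted over the list alone), with a median log2 fold change of -1.75 and a camera adjusted p of 0.0067 with an estimated correlation. The receptor subunit Klrd1 was at 0.285 ± 0.552 CPM (SD, n = 30) in Treg and 25.4 ± 23.7 CPM (SD, n = 10) in Tconv, and granzyme K (Gzmk) at 2.58 ± 4.14 and 28.5 ± 35.7 CPM. Of 4 CD8 and gamma delta T cell markers, 2 were also lower and 0 higher (3 and 0 adjusted over the list alone), with a median of -1.265 (camera adjusted p = 0.0917 with an estimated correlation). Checkpoint and costimulatory receptors went the other way, with 13 of 18 higher and 1 lower, over all genes and adjusted over the list alone alike (adjusted p = 0.015 with an estimated correlation). Ctla4, which strips B7 ligands from antigen-presenting cells, reached 1047 ± 963 CPM in Treg against 222.6 ± 327.5 CPM, and Tnfrsf18 (GITR) 315.4 ± 129.4 against 82.6 ± 44.4 CPM.

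The contrast of tissue with lymphoid Treg asks which genes set Treg of kidney, liver, lung, pancreas, IEL and LPL apart from Treg of blood, spleen and lymph node, with each source weighted equally and Peyer's patch on neither side. Il10 (ENSMUSG00000016529.5, chromosome 1, 131019845 to 131024974), an anti-inflammatory cytokine, rose from 1.55 ± 1.43 CPM (SD, n = 9) in lymphoid Treg to 192.3 ± 273.7 CPM (SD, n = 18) in tissue Treg, a log2 fold change of 5.54 ± 0.48 (SE). Bhlhe40 (ENSMUSG00000030103.11, chromosome 6, 108660629 to 108666925), a transcription factor of resident T cells, rose from 61.9 ± 45.3 to 831.7 ± 624.1 CPM (3.64 ± 0.32). Liver Treg took part in neither rise, with Il10 at 1.05 ± 1.21 CPM and Bhlhe40 at 42.0 ± 5.03 CPM (SD, n = 3). Cxcr6, the receptor for CXCL16, rose by 3.22 ± 0.33, and Itgae, the alpha E chain of the integrin that binds epithelial E-cadherin, by 1.35 ± 0.13, though not in lung Treg on its own. Among lower genes was Ms4a4b, a membrane gene of resting T cells (-1.31 ± 0.10), which did not pass in liver or lung Treg on its own.

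Of 17909 genes tested, 2130 were higher and 1785 lower in tissue Treg, by edgeR's test at an adjusted p of 0.05. Against lymph node alone the balance turned, with 1215 higher and 1683 lower. By p-value the highest-ranked higher genes were the transcriptional repressor Hic1 (3.95 ± 0.31), the pseudokinase Trib1 (1.61 ± 0.13), the endocytic recycling gene Ehd1 (1.81 ± 0.15), the acyl-CoA thioesterase Acot11 (1.65 ± 0.14) and Il10. The lower ones were Ms4a4b, its relative Ms4a4c (-2.51 ± 0.23), the transcription factor Gata1 (-2.18 ± 0.22), the reticulum calcium binder Rcn1 (-1.15 ± 0.12) and the kinase Sgk3 (-1.75 ± 0.18). The 10 genes had edgeR adjusted p-values between 2.22e-08 and 4.83e-07, and Hic1 alone of them passed in liver Treg on its own. The spread behind these tests is that between libraries of 1 source. With counts summed per source, 6 against 3, edgeR called 0 genes, with 2763 at an unadjusted p under 0.05.

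Of 26 residency genes, 19 were higher and 0 lower (20 and 1 adjusted over the list alone), with a median log2 fold change of 1.37 and a camera adjusted p of 0.014 with an estimated correlation. The aryl hydrocarbon receptor gene Ahr, a sensor of dietary ligands, was among them (1.37 ± 0.15), but did not pass in liver or lung Treg on its own. Of 21 measured genes of recirculating T cells, 13 were lower and 0 higher (14 and 0 adjusted over the list alone), and the set test passed with the preset correlation only (adjusted p = 0.17 with an estimated correlation). The IL-6 receptor gene Il6ra fell from 196.5 ± 94.0 to 102.5 ± 77.2 CPM, a difference that did not pass against lymph node alone, and of the single tissues only IEL and LPL passed. Of 30 genes known from tissue Treg, 28 were higher and 0 lower, also when adjusted over the list alone (adjusted p = 0.058 with an estimated correlation). Ccr8, a chemokine receptor of effector Treg, rose by 2.30 ± 0.22 but not in liver Treg (-0.64), and did not pass against lymph node alone. Fgl2, a secreted suppressor molecule, rose by 2.99 ± 0.30.

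Effector genes rose with them. Of 18 cytotoxic and natural killer receptor genes, 11 were higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 0.036 with an estimated correlation), led by granzyme B (Gzmb, 3.66 ± 0.38) and granzyme A (Gzma, 5.47 ± 0.63). Gzmb did not rise in pancreas Treg, with 7.39 ± 4.30 CPM (SD, n = 3) against 10.8 ± 7.68 CPM in lymphoid Treg, and was highest in IEL (3638 CPM) and LPL (1904 CPM). Of 20 cytokine and repair genes, 13 were higher and 0 lower, and the set test passed with the preset correlation only (adjusted p = 0.12 with an estimated correlation). Amphiregulin (Areg), an epidermal growth factor ligand that acts in tissue repair, rose from 3.13 ± 2.78 to 104.4 ± 100.7 CPM, and the secreted factor Metrnl from 3.77 ± 2.79 to 50.3 ± 39.0 CPM. Of 23 AP-1 and early response genes, 20 were higher and 1 lower (median 2.90, adjusted p = 0.075 with an estimated correlation). Junb reached 4985 ± 3266 CPM against 375.6 ± 138.5 CPM, and Fos, the AP-1 subunit that is induced within minutes of stimulation, rose by 4.79 ± 0.54. Areg, Junb and Fos did not pass in liver Treg on its own. Of 30 ribosomal protein genes, 29 were lower and 0 higher (30 and 0 adjusted over the list alone), with a median of -0.83 and an adjusted p of 0.14 with an estimated correlation. Rps20 fell from 371.4 ± 65.9 to 194.1 ± 127.6 CPM, and of the single tissues passed in pancreas, IEL and LPL. The list median was -1.84 in IEL, -1.48 in LPL and 0.049 in lung. The correlation of gene length with each gene's deviation from its mean over all libraries was 0.108 to 0.338 in IEL and LPL Treg. In lung Treg replicates 5 and 6 it was -0.281 and -0.413. The ribosomal fall was not separated from this length trend between libraries. Markers of other cells moved too, with 17 of 21 acinar markers higher and 0 lower (18 and 0 adjusted over the list alone; adjusted p = 0.552 with an estimated correlation), 4 of 22 intestinal epithelial ones higher and 0 lower (4 and 0; 0.504), and 9 of 15 B cell ones lower and 0 higher (9 and 1; 0.303).

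**Figure D2:**
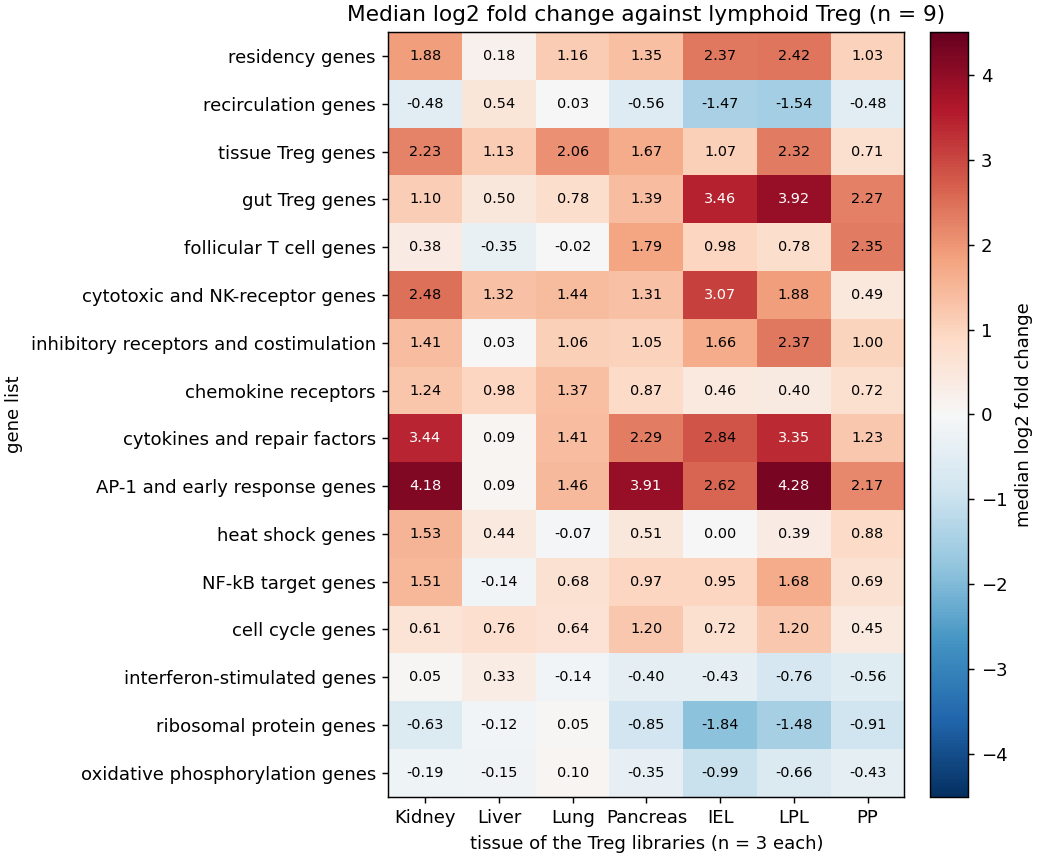
Median log2 fold change of 16 fixed gene lists (vertical axis) in Treg of 7 sources (horizontal axis, n = 3 each) against the 9 lymphoid Treg libraries, as a colour scale with the value in each cell. The early response median was 4.18 in kidney and 4.28 in LPL, and the residency median 2.37 in IEL and 2.42 in LPL.

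Each source was then set against the same 9 lymphoid Treg libraries to give its own profile. In kidney Treg, Ccr8 rose from 69.4 ± 59.8 CPM (SD, n = 9) to 763 ± 415 CPM (SD, n = 3), a log2 fold change of 4.36 ± 0.30, and Bhlhe40 from 61.9 ± 45.3 to 1336 ± 513 CPM (4.99 ± 0.40). Trp53inp2, an autophagy gene, rose by 5.55 ± 0.47. Cstf3, a polyadenylation factor gene, and Ms4a4b were lower (-1.35 ± 0.19 and -1.31 ± 0.19). Of 17909 genes, 2189 were higher and 761 lower by edgeR at an adjusted p of 0.05. The count of called genes was 1802 without kidney Treg replicate 3 and 1606 without replicate 5.

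Of 23 early response genes, 20 were higher and 0 lower (20 and 1 adjusted over the list alone), with a median of 4.18 (camera adjusted p = 0.023 with an estimated correlation), and Jun rose from 23.8 ± 19.8 to 1344 ± 408 CPM and Nr4a1, an orphan receptor induced by antigen, from 161.0 ± 106.2 to 4388 ± 2001 CPM. Among residency genes, 18 of 26 were higher and 0 lower, with a median of 1.88 (adjusted p = 0.013 with an estimated correlation). Of 15 heat shock genes, 10 were higher and 0 lower (13 and 0 adjusted over the list alone), and the set test passed with the preset correlation only (adjusted p = 0.19 with an estimated correlation). Hspa1a, an inducible chaperone gene, rose from 0.827 ± 0.783 to 1378 ± 987 CPM. Ifng, which encodes interferon gamma, rose from 2.06 ± 1.33 to 76.7 ± 57.4 CPM. Transcripts of kidney tubule cells also rose. Gpx3, a peroxidase gene of proximal tubule, reached 199.9 ± 292.7 CPM, with a log2 fold change of 5.96 that was 3.28 without kidney Treg replicate 1. Of 11 tubule markers, 9 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.125 with an estimated correlation). They took 0.274% of all counts in kidney Treg replicate 1 but 0.00598% and 0.00463% in replicates 3 and 5, against 0.00231% to 0.00677% in lymphoid Treg. Higher were also 11 of 19 myeloid, 10 of 13 endothelial and 6 of 10 stromal markers, with 0 lower in each (13, 11 and 8 higher adjusted over the lists alone, and 1 myeloid lower), and camera's adjusted p with an estimated correlation was 0.263, 0.0688 and 0.351. The stromal markers took 0.00939% of counts in replicate 1 and 0.000888% and 0.00291% in replicates 3 and 5, and the shares of the other 2 lists lay within the range of lymphoid Treg.

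Liver Treg had the fewest called genes of the 7 sources, but against spleen alone it had 200 (104 higher, 96 lower) and Peyer's patch Treg 151. Itgb7 (ENSMUSG00000001281.10, chromosome 15, 102215995 to 102231944), the beta 7 integrin chain, stood at 3123 ± 582 CPM (SD, n = 3) against 1534 ± 500 CPM (SD, n = 9), a log2 fold change of 1.09 ± 0.14. Ccr2, the receptor for CCL2, rose from 49.0 ± 27.8 to 252.8 ± 5.50 CPM (2.46 ± 0.33) and the membrane gene Myadm by 2.42 ± 0.33. The splicing regulator gene Hnrnpdl (-1.61 ± 0.18) and Zc3h7a (-1.03 ± 0.15) were lower. Of 17909 genes, edgeR called 175 higher and 32 lower, and DESeq2 called 306 and 213. The count of 207 genes rested on single libraries. It was 103, 96 and 49 without liver Treg replicates 1, 3 and 4, 117 and 118 without blood Treg replicates 4 and 5, 135 and 126 without spleen Treg replicates 2 and 4, and 478 without lymph node Treg replicate 6.

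Chemokine and homing receptors, a list that also holds integrin chains such as Itgb7 and Itgb1, rose in liver Treg. Of 21, 9 were higher and 0 lower (11 and 0 adjusted over the list alone, camera adjusted p = 0.018 with an estimated correlation). Cxcr3, which binds interferon-induced chemokines, rose to 319.8 ± 125.9 CPM from 117.5 ± 50.2 CPM, and Cxcr6 to 112.2 ± 19.7 CPM from 29.7 ± 20.3 CPM. Both calls were lost without liver Treg replicate 4, at log2 fold changes of 1.19 and 1.96, and against spleen alone, at 0.906 and 2.04. Of 26 residency genes, 2 were higher and 0 lower (4 and 0 adjusted over the list alone). Of 21 recirculation genes, 3 were higher and 0 lower (median 0.54, adjusted p = 0.21 with an estimated correlation). Hepatocyte transcripts were present, with 12 of 17 higher and 0 lower (17 and 0 adjusted over the list alone). They took 0.0249%, 0.00633% and 0.0216% of counts in liver Treg replicates 1, 3 and 4. Albumin (Alb) was counted at 40.7 CPM, without the TMM factor, over the 3 liver libraries and at 0 in the 9 lymphoid ones, which made it at least 2340-fold higher against a floor of 3 counts over the group. DESeq2 did not call it.

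In lung Treg, the p53 target Cdkn1a rose from 1.53 ± 0.874 CPM (SD, n = 9) to 79.2 ± 96.5 CPM (SD, n = 3), a log2 fold change of 5.78 ± 0.60. Trp53inp2 rose by 5.08 ± 0.46 and the actin binder gene Tagln2 from 281.6 ± 61.7 to 888.2 ± 73.9 CPM (1.70 ± 0.16). The repair helicase gene Ercc6l2 (-2.23 ± 0.23) and the splicing factor gene Prpf39 (-1.73 ± 0.22) were lower. Of 17909 genes, 1550 were higher and 514 lower by edgeR. The split depended on the tool and the setting. DESeq2 called 1703 higher and 939 lower, a replicate block gave 774 and 831, and the fit without the 6 libraries of the last sample numbers 1221 and 889. Of 30 tissue Treg genes, 27 were higher and 0 lower (28 and 0 adjusted over the list alone), with a median of 2.06 and a camera adjusted p of 0.043 with an estimated correlation. Lgals3, a galectin gene, rose by 3.84 ± 0.44. Of 21 chemokine and homing receptors, 13 were higher and 1 lower (15 and 1 adjusted over the list alone, camera adjusted p = 0.033 with an estimated correlation). The higher ones included Ccr4, which binds CCL17 and CCL22 (182.4 ± 7.74 against 44.3 ± 13.9 CPM). Markers of other cells also rose in lung Treg. Higher were 7 of 19 myeloid, 8 of 13 endothelial, 4 of 6 lung epithelial and 3 of 7 erythroid markers, with 0 lower in each (7, 10, 4 and 6 adjusted over the lists alone), and camera's adjusted p with an estimated correlation was 0.585, 0.19, 0.0771 and 0.281. In replicates 1, 5 and 6 the myeloid markers took 0.0390%, 0.262% and 0.119% of counts and the erythroid ones 0.00521%, 0.0492% and 0.00420%, against at most 0.0941% and 0.0205% in lymphoid Treg. Macrophages also express Lgals3.

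Some lung values rested in large part on replicate 1 of lung Treg. That library was also the only lung Treg library without Xist, a transcript of females, and outside the 6 libraries with the last sample numbers. It also had the highest share of Gm26917 among the lung Treg libraries (1.57% of counts). Ccr7, the receptor that leads T cells into lymph nodes, had a log2 fold change of 2.12 ± 0.56 and one of -0.80 without that library, and S1pr1, the receptor for egress into lymph, had 1.26 ± 0.32 and 0.30. The early response genes Fosb (6.65 ± 0.97) and Fosl2 (5.66 ± 0.77) fell to 1.86 and 1.94, with the Fosb call lost, and Bhlhe40 fell from 3.16 to 1.92, Cdkn1a from 5.78 to 4.01 and Trp53inp2 from 5.08 to 3.87. Of the 23 early response genes, 15 were higher and 1 lower, with a median of 1.46 that was 0.412 without that library.

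In pancreas Treg, Bhlhe40 rose to 1057 ± 88.1 CPM (SD, n = 3) from 61.9 ± 45.3 CPM (SD, n = 9), and Tox2, a factor of follicular T cells, from 40.6 ± 27.7 to 275.8 ± 94.0 CPM (3.09 ± 0.31). Pdcd1, which encodes the checkpoint receptor PD-1, rose by 2.61 ± 0.27 but did not pass against spleen alone. Txnip, an inhibitor of glucose uptake, fell from 1326 ± 690 to 275.9 ± 74.2 CPM (-2.19 ± 0.28) and Ms4a4b had -1.31 ± 0.19. Of 17909 genes, 1367 were higher and 416 lower by edgeR. The count of called genes was 1111 without pancreas Treg replicate 1 and 1082 without replicate 5. Of 16 follicular T cell genes, 10 were higher and 0 lower (11 and 0 adjusted over the list alone), with a median of 1.79 and a camera adjusted p of 0.017 with an estimated correlation. Of 23 early response genes, 19 were higher and 0 lower (20 and 0 adjusted over the list alone; median 3.91, adjusted p = 0.044 with an estimated correlation). Residency genes were higher in 15 of 26 and lower in 0 (19 and 1 adjusted over the list alone; adjusted p = 0.031 with an estimated correlation).

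The 3 higher genes with the smallest p in pancreas Treg were exocrine. They were the lipase gene Pnliprp2 (411.8 ± 330.5 CPM), Cuzd1 (220.0 ± 156.1 CPM) and the zymogen granule gene Gp2 (794.6 ± 699.3 CPM), each under 0.3 CPM in lymphoid Treg. All 21 acinar cell markers were higher, and pancreatic lipase (Pnlip) reached 13640 ± 12460 CPM. The acinar markers took 3.55%, 3.03% and 14.0% of all counts in pancreas Treg replicates 1, 5 and 6, and 1.10% in pancreas Tconv. Of 19 myeloid markers, 7 were higher in pancreas Treg and 0 lower (9 and 1 adjusted over the list alone; camera adjusted p = 0.44 with an estimated correlation), and their share of counts was 0.0568%, 0.138% and 0.0337% in replicates 1, 5 and 6.

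In IEL Treg, Ccr9 (ENSMUSG00000029530.16, chromosome 9, 123678439 to 123784330), the small intestine homing receptor, rose from 10.8 ± 5.73 CPM (SD, n = 9) to 1698 ± 80.5 CPM (SD, n = 3), a log2 fold change of 7.47 ± 0.38. Itgae (ENSMUSG00000005947.11, chromosome 11, 73090583 to 73147446) rose from 173.7 ± 63.0 to 1489 ± 119 CPM (3.15 ± 0.18), Hic1 from 10.1 ± 12.2 to 645.1 ± 13.3 CPM (6.74 ± 0.40), and Gzmb (ENSMUSG00000015437.5, chromosome 14, 56258838 to 56262260) from 10.8 ± 7.68 to 3638 ± 809 CPM (8.49 ± 0.52). The integrin beta 1 chain gene Itgb1 (-3.25 ± 0.30) and the sodium pump subunit Atp1b3 (-2.17 ± 0.18) were lower. Of 17909 genes, edgeR called 2409 higher and 1393 lower. The count of called genes was 2511 without IEL Treg replicate 2 and 2485 without replicate 3.

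Of 20 gut Treg genes, 16 were higher in IEL Treg and 0 lower (17 and 0 adjusted over the list alone), with a median of 3.46 and a camera adjusted p of 0.004 with an estimated correlation. Residency genes were higher in 21 of 26 and lower in 0 (22 and 1 adjusted over the list alone; median 2.37, adjusted p = 0.013 with an estimated correlation), including Prdm1, which encodes the repressor Blimp-1 (3.57 ± 0.35), and Ahr (2.50 ± 0.21). Cytotoxic genes were higher in 12 of 18 and lower in 0 (12 and 1 adjusted over the list alone; median 3.07, adjusted p = 0.0085 with an estimated correlation), with Gzma at 1111 ± 154 CPM. Of 21 recirculation genes, 16 were lower and 0 higher, with a median of -1.47 (adjusted p = 0.067 with an estimated correlation), and Klf2 fell to 150.2 ± 58.0 CPM. All 30 ribosomal protein genes were lower, with a median of -1.84 (adjusted p = 0.082 with an estimated correlation), and the length trend between libraries was not separated from this. Of 22 intestinal epithelial markers, 21 were higher and 0 lower (22 and 0 adjusted over the list alone), with a median of 8.85 (adjusted p = 0.22 with an estimated correlation). They took 0.162% of counts in IEL Treg replicate 3 but 0.00979% and 0.0104% in replicates 1 and 2, against at most 0.00482% in lymphoid Treg. Cd8a, a marker of the cytotoxic lineage, stood at 28.7 ± 9.68 CPM in IEL Treg and at 168 CPM in the single IEL Tconv library.

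In LPL Treg, Il10 reached 748.2 ± 59.0 CPM (SD, n = 3) against 1.55 ± 1.43 CPM (SD, n = 9), a log2 fold change of 9.59 ± 0.60. Ctla4 rose from 314.6 ± 69.1 to 3020 ± 280 CPM (3.26 ± 0.34), Ccr9 to 1005 ± 172 CPM (6.70 ± 0.37), and Areg to 183.7 ± 59.3 CPM. The phosphatase regulator gene Ppp1r10 (2.48 ± 0.14) and Acot11 (3.09 ± 0.19) completed the higher genes with the smallest p, and Ms4a4b (-3.16 ± 0.21) and Atp1b3 (-2.36 ± 0.18) were the lower ones. Of 17909 genes, edgeR called 3117 higher and 1734 lower. Gut Treg genes were higher in 16 of 20 and lower in 0 (median 3.92, camera adjusted p = 0.0054 with an estimated correlation), and residency genes in 22 of 26 with 2 lower (median 2.42, adjusted p = 0.015 with an estimated correlation). Intestinal epithelial markers were higher in 21 of 22 and lower in 0 (22 and 0 adjusted over the list alone; median 9.57, adjusted p = 0.281 with an estimated correlation), with 0.291% of counts in LPL Treg replicate 1 and 0.0343% and 0.00905% in replicates 2 and 3. B cell markers took 0.268%, 0.162% and 0.156% of counts in LPL Treg replicates 1, 2 and 3, against at most 0.149% in lymphoid Treg. The median log2 fold change of that list was nevertheless -1.59. Of 23 early response genes, 19 were higher and 2 lower (median 4.28, camera adjusted p = 0.11 with an estimated correlation). Of 20 interferon-stimulated genes, 11 were lower and 1 higher (12 and 1 adjusted over the list alone), and the set test passed with the preset correlation only (adjusted p = 0.11 with an estimated correlation). Usp18, which damps interferon signalling, fell from 75.2 ± 19.7 to 10.6 ± 2.96 CPM.

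Peyer's patch is a lymphoid organ inside the gut wall, and its Treg carried genes of both settings. The checkpoint receptor gene Lag3 rose from 4.09 ± 3.08 CPM (SD, n = 9) to 74.3 ± 46.2 CPM (SD, n = 3), a log2 fold change of 4.79 ± 0.32. Ccr9 rose to 239.4 ± 46.0 CPM (4.63 ± 0.35), between its lymphoid and its IEL level, and Hic1 to 147.0 ± 19.9 CPM (4.59 ± 0.38). Itgb1 was lower (-2.67 ± 0.29), and the skin homing receptor gene Ccr10 had 0 counts in the 3 Peyer's patch libraries against 10.1 ± 8.0 CPM in the 9 lymphoid ones, which made it at least 247-fold lower. Of 17909 genes, edgeR called 527 higher and 113 lower. The count of 640 genes was 1258 without lymph node Treg replicate 6, and 337 and 419 without Peyer's patch Treg replicates 1 and 3. Of 16 follicular T cell genes, 10 were higher and 0 lower (15 and 1 adjusted over the list alone), with a median of 2.35 and a camera adjusted p of 0.0011 with an estimated correlation. Cxcr5, which guides cells into B cell follicles, reached 250.2 ± 54.0 CPM against 52.9 ± 26.4 CPM, but did not pass against spleen alone. Gut Treg genes were higher in 12 of 20 and lower in 0 (13 and 0 adjusted over the list alone; adjusted p = 0.0067 with an estimated correlation), and intestinal epithelial markers in 8 of 22 and 0 (15 and 0 adjusted over the list alone; adjusted p = 0.334 with an estimated correlation).

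**Figure D3:**
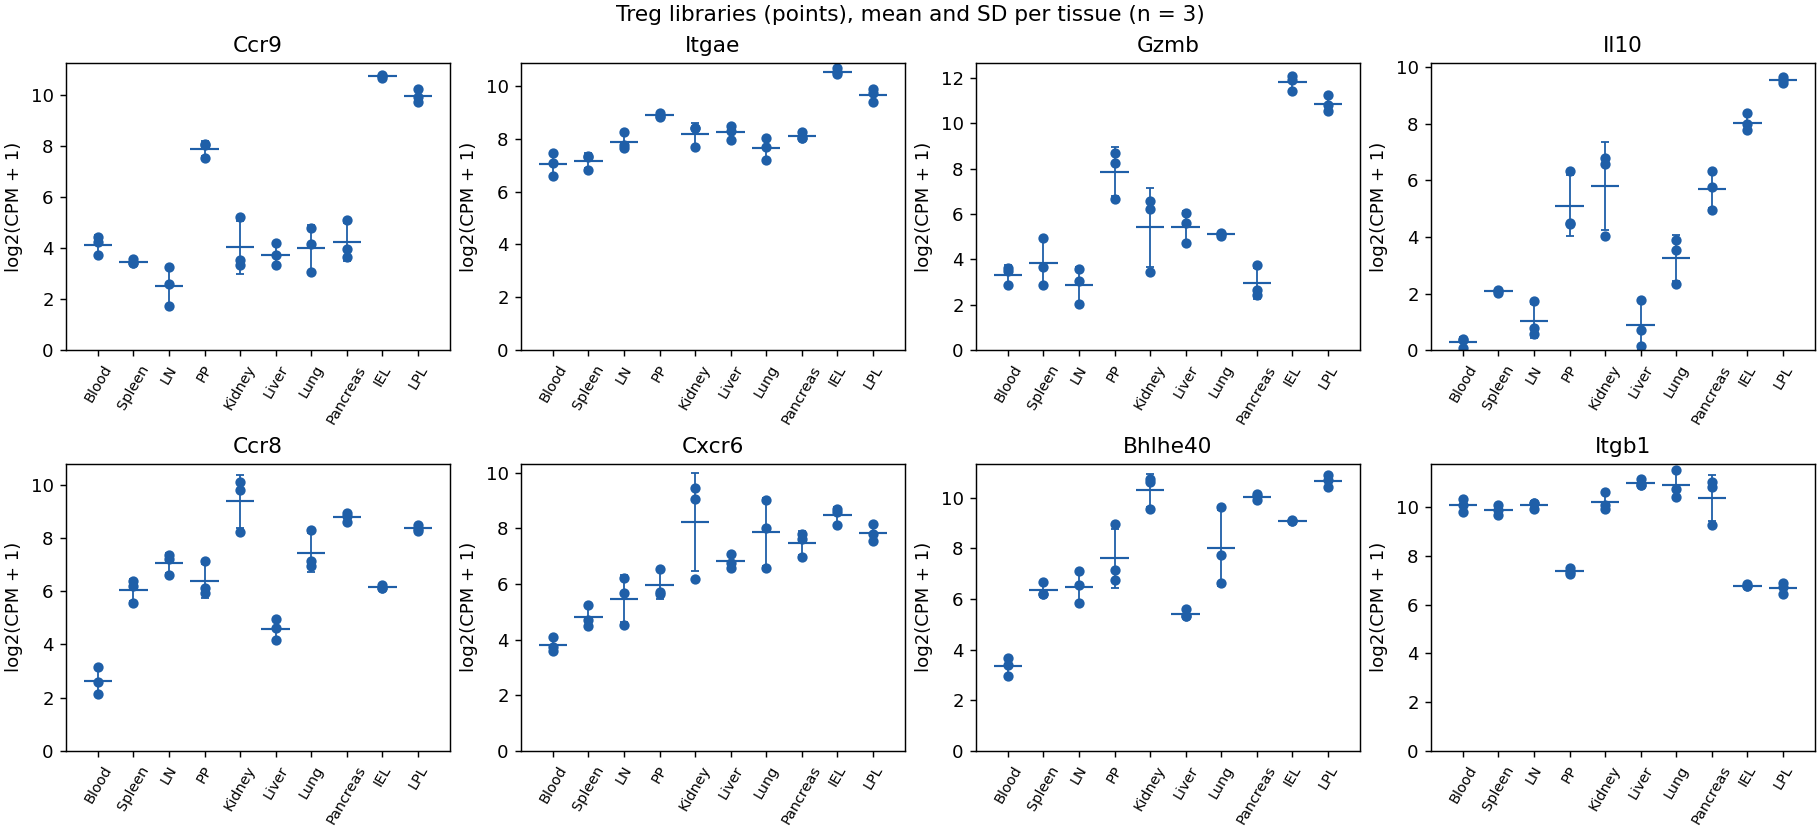
Level of 8 genes as log2(CPM + 1) in each Treg library (points) by source, with the mean and SD of the 3 libraries as bars. Ccr9 averaged 1698 CPM in IEL and 1005 CPM in LPL Treg, and Itgb1 109.0 CPM in IEL Treg.

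A residency program held in common would show as genes that move alike in every tissue. Transferrin (Trf, ENSMUSG00000032554.15, chromosome 9, 103204001 to 103230444), the iron carrier, was higher in each of the 6 tissues, with a log2 fold change of 3.82 (IEL) or more. It stood at 74.3 ± 72.7 CPM (SD, n = 18) in tissue and 4.51 ± 5.22 CPM (SD, n = 9) in lymphoid Treg. Trf is also a member of the fixed list of hepatocyte markers, so RNA carried over from other cells was not separated from its level in Treg. Syndecan 1 (Sdc1), a heparan sulfate proteoglycan, stood at 9.25 ± 8.14 CPM in tissue and 0.342 ± 0.484 CPM in lymphoid Treg. Sdc1 is on none of the marker lists and was highest in LPL Treg (23.0 CPM), and carry-over was not separated from its level either. Cxcr6 (267.2 ± 176.0 against 29.7 ± 20.3 CPM), Metrnl, Gzma, Hic1, Fgl2, Ccr2 and Klf6 were also in the set, and were picked out here after their values were seen unless named above.

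In all, 38 genes passed edgeR's threshold as higher in all 6 comparisons, and 0 as lower. Unchanged groups simulated against the same 9 references gave at most 11 genes shared as higher in 20 runs (median 8.5) and 0 as lower. Independent lists of these sizes would share 0.00331 genes as higher and 6.83e-06 as lower. With the references split into 3 and 6 libraries and 3 tissues set against each part, the median over 20 draws was 11 genes (1 to 17) as higher and 0 as lower. The 10 genes with the largest smallest change were Olfm1, Ces1d, Lrrn2, Rbm47, Ocln, Ermn, Sdc1, Cables1, Deptor and Trf. Olfm1, Ces1d and Lrrn2 had 0 counts in the 9 references and averaged 2.28, 2.09 and 2.14 CPM in tissue Treg, so their place at the top rests on fitted folds that the prior count sets. Ermn, Ocln, Rbm47 and Deptor had 5, 17, 23 and 58 counts over the 9 references, from 2, 4, 3 and 4 libraries. Their fitted folds also rest on few counts. Deptor averaged 0.726 CPM in lung Treg and 0.315 CPM in the references, with a fitted log2 fold change of 3.95. The refit without marker genes of other cell types, which leaves out Trf, had 37 shared genes, 36 of them among the 38. It removes listed genes only, so it cannot decide on carry-over of unlisted ones. Sdc1, Rbm47 and Ocln are unlisted, and were highest in LPL Treg (23.0, 13.6 and 10.8 CPM). Trf and Sdc1 kept the shared call in every leave-one-out fit. Each of the other 8 lost it without 1 or more single libraries, as Olfm1 did without liver Treg replicate 4 (fitted log2 fold change 7.30) or lung Treg replicate 5 (0).

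The shared count was set by liver. Without liver the other 5 tissues shared 332 higher and 18 lower genes, whereas leaving out any other tissue gave between 38 and 45 higher. Gm26917 took 2.12% to 4.67% of counts in all liver Treg libraries and in all blood Treg libraries of the reference. A contribution of that difference between libraries was not separated from the tissue. The count of 38 was 22, 18 and 12 without liver Treg replicates 1, 3 and 4, 20 and 18 without blood Treg replicates 4 and 5, 22 and 21 without spleen Treg replicates 2 and 4, 24 and 25 without lymph node Treg replicates 10 and 7, 22 without pancreas Treg replicate 5, 61 (59 higher, 2 lower) without kidney Treg replicate 1 and 72 without lymph node Treg replicate 6. Against spleen alone, 6 genes were shared as higher and 2 as lower, with 2 of the 6 among the 38. In counts simulated for this design over 17909 genes, 6% of genes changed 2-fold and 72% of genes changed 4-fold in all 6 tissues were recovered as shared.

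The next comparison asks how gut Treg (IEL and LPL) differ from Treg of kidney, liver, lung and pancreas. Ccr9 stood at 1351 ± 398 CPM (SD, n = 6) in gut and 17.1 ± 9.79 CPM (SD, n = 12) in other tissue Treg, a log2 fold change of 6.28 ± 0.31. Gzmb stood at 2771 ± 1118 and 36.6 ± 28.9 CPM (6.53 ± 0.41), and Itgae at 1156 ± 383 and 270.0 ± 64.9 CPM (2.06 ± 0.14). Itgb1 (ENSMUSG00000025809.15, chromosome 8, 128685654 to 128733200) showed the opposite, with 106.1 ± 11.1 CPM in gut and 1693 ± 631 CPM in the other tissues (-3.96 ± 0.23). Ass1, which makes argininosuccinate, fell from 106.6 ± 25.7 to 25.0 ± 1.41 CPM (-2.06 ± 0.12).

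Of 17909 genes, edgeR called 2325 higher and 1901 lower in gut Treg, while DESeq2 called 2164 higher and 2394 lower. Intestinal epithelial markers were higher in 21 of 22 and lower in 0 (22 and 0 adjusted over the list alone; median 6.54, camera adjusted p = 0.246 with an estimated correlation), and were most abundant in IEL Treg replicate 3 and LPL Treg replicate 1. Markers of cells from the other tissues were lower, with 11 of 19 myeloid lower and 0 higher (12 and 0 adjusted over the list alone; adjusted p = 0.205) and 15 of 21 acinar lower and 1 higher (16 and 1; adjusted p = 0.485), by camera with an estimated correlation. Ppp1r10 (1.94 ± 0.11) and the actin regulator gene Abi3 (2.40 ± 0.15) completed the 5 higher genes with the smallest p, and Atp1b3 (-2.16 ± 0.13), AB124611 (-3.84 ± 0.26) and Ms4a4b (-1.99 ± 0.14) the 5 lower ones. Gut Treg genes were higher in 15 of 20 and lower in 1 (median 2.60, camera adjusted p = 0.0067 with an estimated correlation), with Gzma at 897.8 ± 268.1 against 6.49 ± 5.40 CPM. Gpr55, a lipid receptor gene that guides intestinal lymphocytes, stood at 220.5 ± 30.7 and 18.6 ± 8.89 CPM. Of 21 recirculation genes, 16 were lower and 0 higher (17 and 0 adjusted over the list alone), with a median of -1.34 (adjusted p = 0.064 with an estimated correlation). Klf2 fell by 2.58 and S1pr1 by 2.58 on the log2 scale. Of 20 interferon-stimulated genes, 10 were lower and 1 higher (12 and 2 adjusted over the list alone; adjusted p = 0.13 with an estimated correlation). Ifi27l2a, an interferon-induced gene, stood at 90.2 ± 27.0 and 315.4 ± 94.7 CPM.

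The Tconv libraries answer whether conventional cells of the same tissues differ from lymphoid ones in the same way. Bhlhe40 stood at 750.9 ± 674.3 CPM (SD, n = 6) in tissue Tconv and 8.79 ± 6.75 CPM (SD, n = 3) in lymphoid Tconv, and Cxcr6 at 1000.0 ± 608.1 and 56.7 ± 31.1 CPM. Nkg7, a cytotoxic granule gene, stood at 571.4 ± 310.1 and 29.9 ± 15.2 CPM. The 6 CD8 and gamma delta T cell markers also had a positive median, 3.87 (camera adjusted p = 0.26 with an estimated correlation), and Cd8a stood at 168 CPM in IEL and 46.5 CPM in LPL Tconv. Il2ra, the alpha chain of the IL-2 receptor and a classic Treg marker, stood at 52.0 ± 30.3 and 4.79 ± 2.65 CPM, a log2 fold change of 3.45 ± 0.63. With 1 library per source, edgeR called 0 of 14453 genes (smallest adjusted p 0.07), while 2102 had an unadjusted p under 0.05. DESeq2 called 1085 and limma-voom 1336, and the fit of all 40 libraries called 1750. Without pancreas Tconv replicate 5 edgeR called 118. In counts simulated for this design over 14453 genes, edgeR recovered 0% of genes changed 2-fold and 3% of those changed 4-fold.

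The tissue effects of both cell types ran together across genes. Over 14300 genes the log2 fold changes of Treg and Tconv had a Pearson correlation of 0.677 and a Spearman correlation of 0.593, which are across genes, and genes are not independent replicates. Of the 1984 genes higher in tissue Treg that were also measured in Tconv, 1830 (92.2%) moved the same way in Tconv, and of 1625 lower ones 1420 (87.4%) did. Among genes not called in Treg the share with the same sign was 65.5%. Both cell types shared transcripts of other cells, as with acinar markers in pancreas. The libraries with the last sample numbers, from lymph node and lung, also held both. The agreement was not separated from these.

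The last comparison tests whether the tissue effect differs between Treg and Tconv. Each Tconv group held 1 library, so the p-values and SE of this comparison rest on the spread between Treg libraries. The Tconv libraries were assumed to vary like them. Il2ra (ENSMUSG00000026770.5, chromosome 2, 11642807 to 11693193) gave the smallest p. It was lower in tissue than in lymphoid Treg (348 against 554 CPM) and higher in tissue than in lymphoid Tconv (52.0 against 4.79 CPM), a difference of -4.19 ± 0.28 on the log2 scale. Il2rb, the beta chain shared by the IL-2 and IL-15 receptors, was level in Treg (1771 against 1778 CPM) and higher in tissue Tconv (1419 against 174 CPM; -2.81 ± 0.21). Socs2, a target of the same signal, stood at 44.9 against 35.6 CPM in Treg and at 44.9 against 1.05 CPM in Tconv (-4.81 ± 0.36). Entpd1, which encodes the ectonucleotidase CD39, stood at 92.5 against 56.0 CPM in Treg and 53.6 against 3.23 CPM in Tconv (-2.998 ± 0.249).

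**Figure D4:**
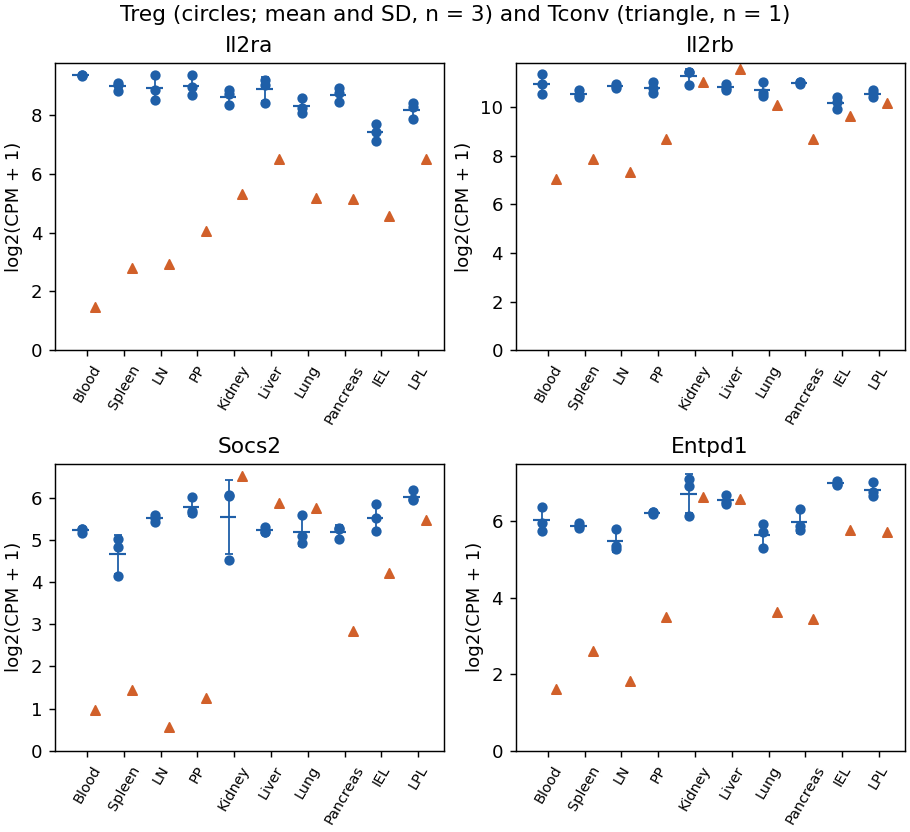
Level of Il2ra, Il2rb, Socs2 and Entpd1 as log2(CPM + 1) by source, with Treg as circles (bars are the mean and SD, n = 3) and the single Tconv library as a triangle. Il2ra averaged 554 CPM in lymphoid and 348 CPM in tissue Treg, and 4.79 CPM in lymphoid and 52.0 CPM in tissue Tconv.

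Of 17924 genes, edgeR called 72 with a more positive and 153 with a more negative tissue effect in Treg. The 5 more negative genes with the smallest p were Il2ra, Socs2, Il2rb, Entpd1 and Itgae (-3.24 ± 0.30), and the Itgae value was -1.82 without lymph node Tconv replicate 8 and did not pass in limma-voom. The 5 more positive ones were Wdr90 (3.38 ± 0.50), the selenium carrier Selenop (1.24 ± 0.19), the kinase Sgk1 (1.92 ± 0.31), the costimulatory receptor Cd27 (1.29 ± 0.21) and Zgpat (1.09 ± 0.19). Wdr90 fell to 1.49 and lost its call without lung Tconv replicate 5. Cd27 stood at 242 against 262 CPM in Treg and at 110 against 251 CPM in Tconv, and Sgk1 at 94.7 against 32.1 CPM in Treg and 97.6 against 118 CPM in Tconv. Of 25 Treg signature genes, 7 were more negative and 0 more positive (14 and 0 adjusted over the list alone), with a median of -0.74 and a camera adjusted p of 0.013 with an estimated correlation. Of 18 cytotoxic genes, 3 were more negative and 0 more positive (6 and 0 adjusted over the list alone; median -1.43, adjusted p = 0.004 with an estimated correlation). The 6 CD8 and gamma delta T cell markers had a median of -2.87, with 1 more negative and 0 more positive, also adjusted over the list alone (camera adjusted p = 0.0076 with an estimated correlation). The call of Nkg7 among the cytotoxic genes (-2.31 ± 0.53) was lost without blood Tconv replicate 5 or lymph node Tconv replicate 8. The early response list had 0 genes called by edgeR in either direction, with a median of -0.131.

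The count of 225 genes was 122 without blood Tconv replicate 5, 400 (204 more positive, 196 more negative) without lymph node Treg replicate 6 and 369 without pancreas Tconv replicate 5. With 4 class means in place of the source means, 7 genes were called, and Il2ra, Il2rb, Socs2 and Entpd1 were the named genes that passed there. In counts simulated for this design over 17924 genes, 9% of genes changed 2-fold and 71% of genes changed 4-fold were recovered.

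The early response list was also followed source by source, since it was high in several tissues. Its mean log2 CPM in Tconv left a gap of 1.47 between 6 lower sources (blood, spleen, lymph node, liver, lung and Peyer's patch) and 4 higher ones (kidney, pancreas, IEL and LPL), and the Treg means of the same 4 sources were also the highest. Within the 6 lower sources the Treg and Tconv means had a Pearson correlation of 0.542 (exact permutation p = 0.278, two-sided) and a Spearman correlation of 0.2 (exact permutation p = 0.714). The 4 higher sources were too few for a correlation of their own. This was the 1 relation across sources that was computed.

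**Figure D5:**
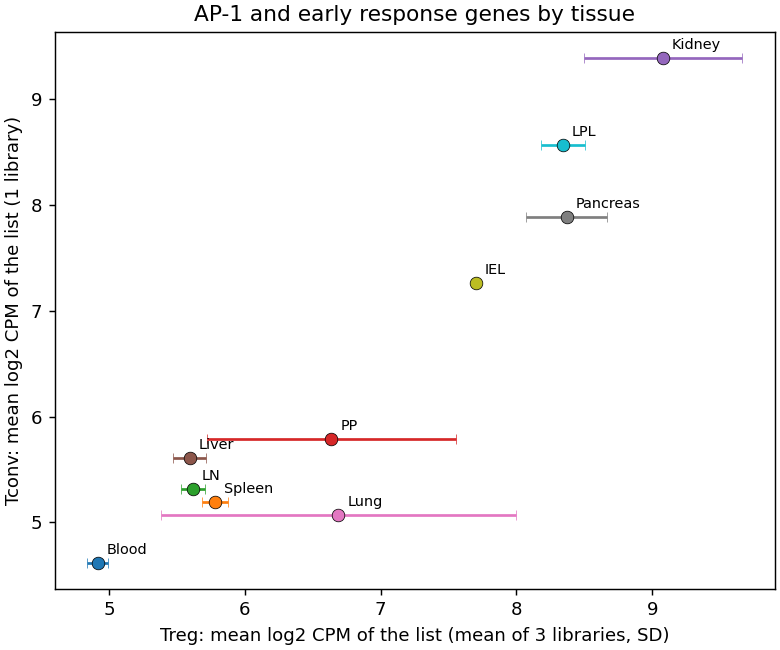
Mean log2 CPM of the early response genes in Tconv (vertical axis, 1 library per source) against the mean of the 3 Treg libraries of the same source (horizontal axis, bars are the SD), over 10 sources. Kidney, pancreas, IEL and LPL lie above a gap of 1.47 in Tconv.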

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

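The tests of Treg in the Tconv gate, of a heat shock response and of single libraries were chosen after the result was seen, whereas the relation of the early response across sources, the splits and the comparison of tissue effects were planned.

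The tissue effect differed between Treg and Tconv at 225 genes by edgeR's test of the difference. Among the genes named for it, the difference was -4.19 for Il2ra, -2.81 for Il2rb, -4.81 for Socs2, -3.0 for Entpd1 and -3.24 for Itgae. It was 3.38 for Wdr90, 1.24 for Selenop, 1.92 for Sgk1, 1.29 for Cd27 and 1.09 for Zgpat. Of the 84 ways to set 6 of the 9 sources against 3, 5 gave at least as many genes as the real 225, and the highest other gave 303, so that chance cannot be excluded for the count.

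The mean levels of Il2ra, Il2rb and Socs2 were higher in tissue than in lymphoid Tconv, although edgeR called 0 genes there, with 2102 at an unadjusted p under 0.05 (DESeq2 1085, limma-voom 1336). If Treg in the Tconv gate had brought them, Foxp3 would have come along at the same share of the Treg level. Tissue Tconv held 0.701% of the Foxp3 of tissue Treg, against 14.9% of the Il2ra, 80.1% of the Il2rb and 100% of the Socs2, which argues against Treg in the gate as the source of the difference. Activated conventional cells, which also carry Il2ra, remain a candidate explanation that the design does not test.

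Foxp3 in lung Tconv replicate 5, at 6.77 CPM without the TMM factor, stood apart from the other 9 Tconv libraries, which lay between 0.179 and 1.35 CPM on the same scale (Dixon ratio 0.823, critical value 0.466). It was the 1 library flagged in 20 checks, over 10 groups, for a sample far from its group. Chance alone would pass the critical value in about 1 in 20 groups, and the ratio lay well beyond that value. No explanation was tested for this library.

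The early response genes rose in Treg of kidney (median 4.18), pancreas (3.91), IEL (2.62) and LPL (4.28), with camera adjusted p of 0.0229, 0.0436, 0.125 and 0.114 with an estimated correlation, while the median in liver was 0.085. Tissue digestion acts on both cell types of a source, and over the 10 sources the list mean in Tconv followed that in Treg (Spearman correlation 0.818, permutation p = 0.00531), which is consistent with handling shared by both cell types. The relation lay between the 4 high and the 6 low sources, since within the 6 low ones the correlation was 0.2. A heat shock response did not come with it in every tissue. Outside lung, whose rise rested on a single library, 4 tissues had an early response median above 1. The heat shock median was below 0.5 in 2 of the 4 (0.002 in IEL and 0.386 in LPL) and 1.53 in kidney. In pancreas (0.506) it rested on replicate 6, with a list mean of 8.59 against 5.99 and 5.95 in replicates 1 and 5. The rule set for the tissues together gave no answer. A stimulus in the tissue itself that reaches Treg and Tconv alike predicts the same relation and stays open.

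In lung, the rise of the early response list may come from a single library. Its median of 1.46 was 0.412 without lung Treg replicate 1, and between 1.81 and 1.83 without another lung library. Replicate 1 was also the only lung Treg library that did not express Xist and lay outside the 6 libraries with the last sample numbers. Gm26917 took 1.57% of its counts, against 0.272% and 0.305% in replicates 5 and 6. Its difference from them therefore cannot be told apart from sex, from that set of libraries or from what lies behind this share. In Peyer's patch the median was 0.793 without Peyer's patch Treg replicate 1 and between 2.25 and 2.38 without another, so a single library as the cause cannot be told apart there from a smaller rise in all 3 libraries. Replicate 1 also had 3.56% of counts in Gm26917, against 0.869% and 0.67% in replicates 2 and 3.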

How the results depend on the processing

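The term for Xist-expressing libraries, the omission of the 6 libraries with the last sample numbers and the omission of a tissue from the shared set were chosen after the data had been seen. DESeq2 size factors kept every count of called genes within 1.5 times, moved the median of all genes by at most 0.022 in size (-0.022 in liver), and changed the share of higher calls by less than 10 percentage points. Removing the listed marker genes of other cell types also kept every count within 1.5 times, but leaves in unlisted genes of such cells. Without the filter on low counts, the comparison of tissue with lymphoid Tconv gave 16 genes in place of 0.

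DESeq2's test gave 519 genes in liver (306 higher, 213 lower), 1089 in Peyer's patch, 599 for the difference of tissue effects, 1085 in Tconv and 71 shared genes, 36 of them among the 38. The split of higher and lower genes moved by more than 10 percentage points with DESeq2's test in kidney (2024 and 1144), pancreas (1428 and 790), IEL (2157 and 1929) and Peyer's patch (715 and 374), as well as in liver and lung (1703 and 939). With limma-voom, 6116 genes were called for tissue Treg, 6703 for gut Treg and 1336 in Tconv, and the difference of tissue effects split into 189 and 132. The cause was not tested. Tconv gave 1750 genes in the fit of all 40 libraries, where the spread between Treg libraries enters. A fold change of at least 2 left 993 genes for Treg against Tconv, 1608 for tissue Treg and 2081 for gut Treg by construction.

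Against spleen alone, which leaves 3 reference libraries, the counts were 1370 for tissue Treg, 1033 in kidney, 200 in liver (104 higher, 96 lower), 1299 in lung, 365 in pancreas, 1414 in IEL, 2257 in LPL, 151 in Peyer's patch and 8 shared genes (6 higher, 2 lower), with 2 of the 6 among the 38. Against blood alone tissue Treg had 2124, and against lymph node alone 1215 higher and 1683 lower. Summed counts per source, 6 against 3, gave 0 genes by edgeR, with 2763 at an unadjusted p under 0.05 and a smallest adjusted p of 0.123. With 4 class means the difference of tissue effects had 7 genes. The set tests fell from 225 calls to 29 with an estimated correlation.

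Libraries of different sources share replicate numbers, and the labels do not say what a number stands for. The 58 pairs of Treg libraries with the same number had a mean correlation of deviations of -0.0258 (-0.473 to 0.19), 6 of them above 0.1, and 7 of 28 libraries lay nearest to their own number. With the number as a replicate block the counts were 1598 for tissue Treg, 992 in kidney, 8 in liver, 1605 in lung (774 higher, 831 lower, against 1550 and 514 without the block), 471 in pancreas, 1504 in IEL, 2311 in LPL, 152 in Peyer's patch, 2168 for gut Treg and 2 shared genes, 1 of them among the 38. Pairs of the same source and number gave 618 genes for Treg against Tconv.

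A term for Xist-expressing libraries gave 469 genes in liver and 147 in Tconv. With that term lung split into 1200 higher and 720 lower genes, pancreas into 1561 and 783, and Peyer's patch into 648 and 263. Without the 6 libraries of the last sample numbers there were 389 genes for the difference of tissue effects (196 more positive, 193 more negative), 23 shared genes, 18 of them among the 38, and 1 in Tconv. Higher and lower genes then numbered 180 and 74 in liver and 1221 and 889 in lung. The shared set without liver had 350 genes. The cause was not tested.

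Leaving out 1 library at a time gave 2235 to 2833 genes for Treg against Tconv, 3145 to 4540 for tissue Treg, 1606 to 3465 in kidney, 49 to 478 in liver, 1582 to 3004 in lung, 1082 to 2615 in pancreas, 2485 to 4549 in IEL, 3467 to 5482 in LPL, 337 to 1258 in Peyer's patch, 3343 to 5008 for gut Treg, 0 to 118 in Tconv, 122 to 400 for the difference of tissue effects, and 12 to 72 shared genes. The libraries behind the moves beyond 1.5 times are named with their values in the report. The distances between Treg libraries kept their direction, with differences of -32.19 over 2000 genes and -0.029 for 1 minus the Spearman correlation.

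The 250 results for genes chosen by the naming rule, not all of them printed, were refitted in 7852 settings in all. In 7527 they kept their side of the threshold, in 282 they no longer passed and in 42 they newly passed. In 1 the direction reversed for a result that passed in at least 1 of the fits. Changes of direction where neither fit passed were counted among the 7527. That was Ccr7 in lung Treg, at 2.12 with all libraries, -0.796 without lung Treg replicate 1 and 2.647 without lung Treg replicate 5. All named genes of the tissue Treg comparison lost their call with summed counts. In simulated counts for kidney Treg over 17909 genes, 29% of genes changed 2-fold and 81% changed 4-fold were recovered, which bounds what 3 libraries against 9 could show.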

Other observations

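The tests on gene length were chosen after the result was seen, and the splits were planned.

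Peyer's patch Treg shared the low Itgb1 of IEL and LPL Treg (109 and 103 CPM), with 164.0 ± 15.3 CPM (SD, n = 3) against 1042 ± 157 CPM in lymphoid Treg (SD, n = 9), together with a Hic1 level of 147.0 ± 19.9 CPM that lay between lymphoid and IEL Treg. Among the 10 sources Il2ra was lowest in IEL Treg (171.9 ± 33.7 CPM, SD, n = 3) and highest in blood Treg (656.3 ± 8.53 CPM, SD, n = 3).

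Other splits of the same samples were counted for each comparison. For Treg against Tconv, 1 of 60 splits, the real one, gave as many genes (2565, highest other 4), which excludes chance. For tissue against lymphoid Treg, 1 of 100 splits of single libraries did (2737, highest other 233). Those splits break up the sources, so they cannot decide whether chance explains the grouping of sources. At the level of sources 5 of 84 did (3915, highest other 5513), so chance cannot be excluded. The highest of those splits set kidney, IEL and LPL apart from the rest, and next came pancreas, IEL and LPL (5412), kidney, pancreas and LPL (4301), and lung, blood and lymph node (4028). The first 3 of these are drawn from the 4 sources with the highest early response means, which form a structure of samples of their own. Of 40 splits of libraries each, only the real one reached its count for kidney (1663, highest other 333) and pancreas (855, highest other 2). The same held for IEL (2893, highest other 12) and LPL (3895, highest other 128). Those splits regroup single libraries, so they do not measure chance at the level of sources. For gut Treg by libraries 1 of 40 reached the count (2557, highest other 156), with the same limit. The 15 splits of 6 tissues are too few for a share under 0.05, and there gut Treg had 4226 genes and the highest other split 3665. In Tconv the real split gave 0 genes (highest other 81), so that all 84 splits had to reach it and the count decides nothing.

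For liver 2 of 40 splits gave as many genes (60, highest other 921), for lung 2 of 40 (440, highest other 534) and for Peyer's patch 2 of 40 (287, highest other 929), so chance cannot be excluded for these counts. In each of the 3 the highest split set lymph node Treg replicates 7 and 10 apart, joined by spleen Treg replicate 3 or lung Treg replicate 5, and in liver and Peyer's patch it called several times the real count, which points to a structure among the reference libraries. Without the 6 libraries of the last sample numbers, which include these, the counts in the fit of all Treg were 254 in liver, 2110 in lung and 627 in Peyer's patch, but only 137 of the 207 genes in liver, 880 of the 2064 in lung and 476 of the 640 in Peyer's patch were among them.

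Those 6 libraries, lymph node Treg replicates 7 and 10, lymph node Tconv replicate 8, lung Treg replicates 5 and 6 and lung Tconv replicate 5, had fewer counts of long genes. The correlation of gene length with each gene's deviation from its mean over all libraries ran from -0.413 to -0.281 in them. The sex of the animals does not account for the fewer counts of long genes, since the other libraries that express Xist had correlations of 0.0868 or more. Neither does the tissue, since lymph node Treg replicate 6 and lung Treg replicate 1 had correlations of 0.0142 or more. The sample numbers of the 6 follow each other and only 1 other library, liver Treg replicate 4, lay below -0.2. A shared step of library preparation would predict this. Lars2, mt-Rnr2, Mir6236, Gm23935 and CT010467.1, transcripts that resemble ribosomal RNA, together took 2.6% to 6.3% of counts in the 6. Liver Treg replicate 4 had 4.25%, the highest of the other libraries, and Gm26917 was not in this sum. Spleen Treg replicate 3 (3.6%) and blood Treg replicate 2 (3.2%) exceeded lung Treg replicate 5 (2.6%). Their length correlations were -0.102 and 0.0154, against -0.281 in that lung library. A cause tied to that share was not separated from a shared step. The labels give no date or batch, so a shared step of library preparation remains a hypothesis.

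Xist, transcribed from the inactive X chromosome of females, stood at 54.1 to 228 CPM in 10 libraries and at most at 0.481 CPM in 30, while the labels give no sex. The 10 were all 4 lymph node libraries, 3 of the 4 from lung and 3 of the 4 from pancreas, so sex is confounded with tissue, and all 3 lymph node libraries among the 9 references of the Treg comparisons are female by this measure. Gm26917 took 1.37% to 4.67% of counts in all blood and liver Treg libraries. Kidney, lung and Peyer's patch Treg replicate 1 and pancreas Treg replicate 6 also lay in that range. Every other library had at most 0.869%. The cause was not tested, and in blood and liver Treg it cannot be told apart from the source. The heat shock gene Hspa1a was highest in the kidney Tconv library (3091 CPM) and in kidney Treg replicate 3 (2158 CPM).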
